A study of Arabidopsis thaliana with 24 samples.

How the data were processed

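RNA from 9-day-old Arabidopsis thaliana seedlings was measured on 24 Agilent 2-colour arrays. Each array set cDNA of submerged seedlings against cDNA of unsubmerged control seedlings of the same genotype. The genotypes were Columbia, the wild type, and wrky22-ko2, a T-DNA insertion line of the transcription factor gene WRKY22. Seedlings on plates were placed for 1, 3 or 6 h into half-strength MS liquid medium bubbled with 3% oxygen, so that submergence came with low oxygen. The labels name the tissue seedling, while the extraction protocol names shoots or roots, so which part of the plant was extracted is open. The labels give no time for the control samples. If these were taken at another hour than the submerged ones, hour of harvest and submergence cannot be told apart. Each of the 6 groups (genotype by time) had 4 biological replicates, which the labels describe as grown, treated and harvested independently. The submerged sample carried Cy5 in replicates 1 and 3 and Cy3 in replicates 2 and 4. Each group was hybridized on a slide of its own, and the 6 slides were scanned on 4 days, none of which held both genotypes. At a single time, slide, scan day and genotype can therefore not be told apart.

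Per the file headers, the scanner files came from Feature Extraction 10.7.1.1 and hold the median intensity of each spot in each dye and the median local background intensity, in scanner units without normalization. They also hold processed signals, intensities that Feature Extraction had background-subtracted with spatial detrending and normalized between dyes. Per the file headers, a log10 ratio of Cy5 over Cy3 had been computed by Feature Extraction from these background-subtracted and dye-normalized signals. The deposited value table of the authors holds log2 ratios of submerged over control. It has 43663 values per array. Those of probes spotted once, controls left out, matched the processed signals, turned on the dye-swapped arrays, to within 2.99e-06 on the log2 scale. Its other values were not compared. The ratios of the value table were not centred, with array medians from -0.27 to 0.17. Other columns of the scanner files, per the file headers, hold other values, namely flags of 0 or 1 for spots above background, non-uniform or saturated.

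The median signals were used, since the files hold no mean signals, although mean signals had been chosen at first. Signals were corrected with normexp (offset 50) and normalized within each array by loess, with control spots given no weight, in limma 3.58.1 under R 4.3.3 (statmod 1.5.0, data.table version 1.17.8, jsonlite 2.0.0). Spots flagged as outliers were left out, and spots of a probe were averaged. Of 43603 probes, 34358 matched 1 locus of the TAIR10.1 annotation, which served for names only, and these covered 25433 loci. The other 9245 probes were tested apart. A gene was represented by its brightest probe over all arrays. Genes had to be well above background in at least 4 of the 48 channels, which 20834 were, and to have at least 2 unflagged arrays in every group. This second condition was added after the data were seen and left out 527 genes, so that 20307 were tested. Of the ratios, 0.824% were missing.

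Between 57.9% and 84.7% of spots per array were well above background in green and between 43.5% and 72.6% in red, and 0 spots were saturated. Flagged outliers made up 0.0365% to 5.11% of spots. The number of arrays limits the precision of each value. Within groups, array ratios correlated across genes with a median r of 0.78 over 36 pairs (range 0.54 to 0.90), where genes are not independent replicates. No pair of arrays held identical values. Replicates 1 and 2 of wrky22-ko2 at 6 h were doubted for their signals over background, the highest in green and the lowest in both dyes, and results were also computed without them.

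A limma model was fitted to all 24 arrays, with the 6 submergence effects and a dye effect for each gene, leaving 17 residual degrees of freedom. It gave the effect in each group, the difference between the genotypes at each time (wrky22-ko2 minus Columbia), and 6 h against 1 h in each genotype. The mean difference over the 3 times and the comparison of control channels (after Aquantile normalization between arrays) used slide as a random block. P-values were adjusted by the Benjamini-Hochberg method over the tested genes of a comparison, and genes with an adjusted p under 0.05 were called. All tests were two-sided. A fold change is given as at least a size where the dimmer channel was well above background on none of the 4 arrays of a group.

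Before the data were examined, the comparisons, tests, threshold, gene lists, alternative settings and the rule for named genes were fixed. There were 15 gene lists, 13 of named loci and 2 defined by a rule on reference names (the WRKY family without WRKY22, and cytosolic ribosomal proteins). Members were matched by locus and kept where the given symbol belonged to that locus in the annotation, which kept 329 of 337, and 301 were tested. Some loci stand in several lists, such as the sucrose synthases and fermentation enzymes in the core oxygen-deprivation and glycolysis lists. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 135 tests of 15 lists and 9 comparisons, and missing ratios were replaced there by fitted values. Camera compares a list with all other tested genes. The same tests were run with an estimated correlation and with fry, which asks whether the genes of a list move on balance 1 way without comparing them with others. To ask whether a general compression of ratios accounts for differences between the genotypes, the Columbia changes were also multiplied by the slope of the first principal axis of the 2 genotypes' changes over all tested genes, and the differences were tested again. After this scaling, list tests were adjusted over the 15 lists of a time and not over the 135 tests, so the thresholds are not alike. The scaled tests of single genes also used fitted values in place of missing ratios, unlike the main tests. This can narrow the standard errors of genes with missing ratios. Calls of list members are also given adjusted over the list alone.

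Named genes were WRKY22 and, for each submergence effect, the 8 largest rises and 8 largest falls among called genes that moved the same way on all 4 arrays and were well above background in the brighter channel on all 4. For each difference between genotypes they were the 10 largest each way among called genes whose array ratios did not overlap between the genotypes, or, where fewer than 10 genes passed, the 10 of lowest p. For the mean difference they were the 10 largest called each way, for 6 h against 1 h and for the control channels the 8 largest called each way, and for each list up to 6 called members with the largest change. Genes are named by the symbol of the annotation or, where it gives none, by locus.

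Whether replicate numbers pair arrays across groups was checked from the deviations of array ratios from group means, since the labels do not say that a number marks a shared batch. Arrays of the same number in the 2 genotypes deviated together at every time, with correlations across genes from 0.153 to 0.472 at 1 h, 0.257 to 0.502 at 3 h and 0.372 to 0.516 at 6 h. The same held for Columbia at 1 h and 6 h (0.217 to 0.288) but not for the ratios of wrky22-ko2, where 1 of the 4 correlations was -0.129, although its control channels at 1 h and 6 h did deviate together (0.258 to 0.614). Control channels of the same number were also closer across the times of a genotype (median SD of the difference 0.228 against 0.364 for other numbers of the same dye in Columbia, and 0.467 against 0.555 in wrky22-ko2). Whether control RNA was shared between arrays is not stated, and the effects at the 3 times may then not be independent of each other.

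These alternative settings were no background correction, Feature Extraction processed signals, the authors' values, median centring in place of loess, scale normalization between arrays (quantile for control channels), flagged spots kept, no filter and a stricter filter on dim probes, the mean of a gene's probes, no dye term, only the groups compared, a replicate block, array weights, a trended and robust variance prior, a change of at least 2-fold, no slide block, and leaving out each array. Added after the data were seen were the replicate block within each time, with and without scale normalization, scan day as a random block, control channels or ratios averaged per number over the times, the arrays doubted above left out, and some of these for the gene lists. On simulated data built from the residual spread, the fit recovered 74.6%, 98.5% and 100% of added changes of 0.5, 1 and 2 on the log2 scale in the Columbia 6 h effect, with 6.67% false calls, and 32.8%, 92.5% and 100% in the difference at 3 h, with 4.46% false calls. At 3 h, simulated differences between genotypes of 0.5 on the log2 scale were thus more often missed than called. The mean difference recovered 88.1% of changes of 0.5 with 11.9% false calls, and the control channels 68.7% with 10.8%. The simulated noise did not hold the deviations that real arrays of the same replicate number shared. The rates therefore need not hold for the real arrays.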

Results

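Transcript levels were compared between submerged and unsubmerged Arabidopsis seedlings of the wild type Columbia and of wrky22-ko2, an insertion line of WRKY22, at 1, 3 and 6 h. The title of the series names targets of WRKY22 under submergence as its subject. Each of the 6 groups held 4 arrays, and each array carried 1 submerged and 1 control sample of the same genotype. The median signal per array ranged from 82 to 200 scanner units in green and from 93.5 to 183 in red, against local background medians of 25 to 37 and 53 to 58. Of the genes on the array, 20307 were tested. Changes are log2 ratios of submerged over control with their standard error from limma and n = 4 arrays per group, unless stated otherwise.

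WRKY22 (AT4G01250), the transcription factor gene that the line is named for, rose strongly in submerged Columbia and little in wrky22-ko2. In Columbia it was 26.6-fold higher than control at 1 h (log2 4.74 ± 0.26), 19.2-fold higher at 3 h and 12.6-fold higher at 6 h, on 4 of 4 arrays each. In wrky22-ko2 the rises were 1.79-fold, 1.64-fold and 1.92-fold. The channels differed in both states: the log2 control signal was 8.33 ± 0.56 (SD, n = 12 arrays) in Columbia and 10.48 ± 0.51 in wrky22-ko2, and the submerged signal was 12.55 ± 0.47 and 11.31 ± 0.37. WRKY22 was thus 4.44-fold higher in the control channels of wrky22-ko2 (adjusted p = 1.5e-04), and its response to submergence differed from that of Columbia by -3.90 ± 0.37 at 1 h (adjusted p = 8.8e-06), -3.55 at 3 h and -2.71 at 6 h in log2 terms. The gene was measured by 1 probe, which was well above background on all arrays. The position of this probe relative to the insertion is not known, so that its signal says nothing on whether a functional transcript was lost.

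**Figure D1:**
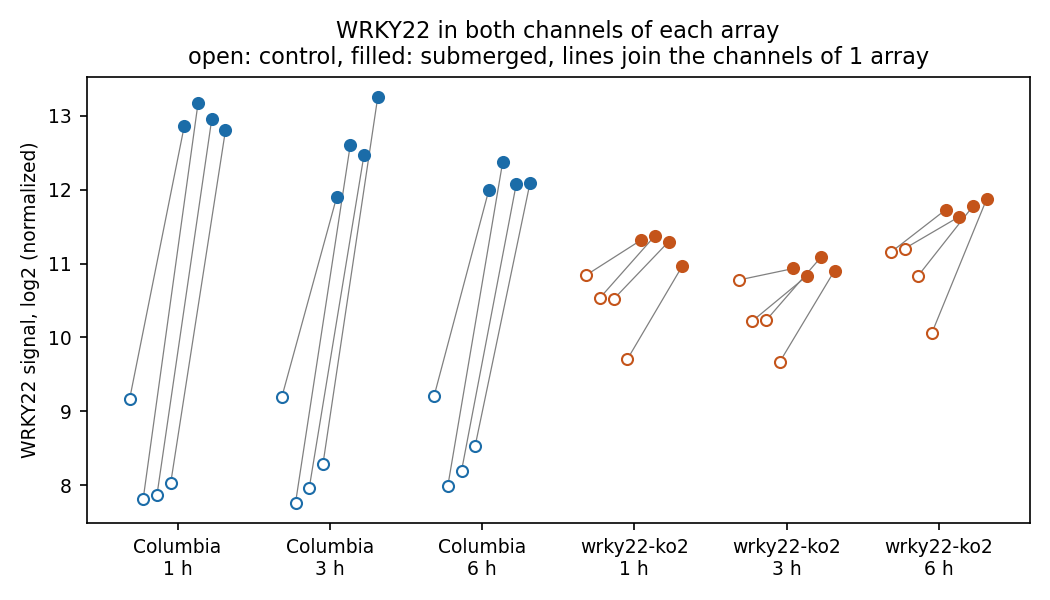
Normalized log2 signal of WRKY22 in both channels of each of the 24 arrays, by group (x axis). Open points are control channels, filled points submerged channels, and a line joins the channels of 1 array. Control signals in Columbia lie between 7.76 and 9.21 and those in wrky22-ko2 between 9.67 and 11.20.

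After 1 h of submergence, the largest rises in Columbia were in AT4G10270 (log2 4.91 ± 0.34, 30-fold), AT2G32200 (4.90 ± 0.33), CML38, a calmodulin-like protein (4.81 ± 0.26), AT1G33055 (4.77 ± 0.37) and CYP81F2, a cytochrome P450 of indole glucosinolate synthesis (4.70 ± 0.39). AT3G55840 (4.66) and AT4G24110 (4.35) followed. Among the falls were the transcription factors GPRI1 (-2.36 ± 0.20) and GLK2 (-2.31 ± 0.33), which promote chloroplast development, the auxin-responsive SAUR genes AT4G38860 (-2.73), AT4G38840 (-2.08) and SAUR20 (-1.92), the B-box gene BBX15 (-2.10), AT2G15020 (-2.08) and CYP706A6 (-1.93). In all, 5426 genes changed, 2965 up and 2461 down, and 947 of them changed at least 2-fold, 800 up and 147 down. The share of rises depended on the normalization: 54.6% of changes were rises with loess and 20.0% of 9584 with median centring, which moved the median of all genes to -0.18.

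After 3 h in Columbia, NIP2;1, an aquaporin that passes lactic acid, rose 68.1-fold (6.09 ± 0.28), ADH1, the alcohol dehydrogenase, 63.9-fold (6.00 ± 0.38), HB1, a haemoglobin, 57.1-fold (5.84 ± 0.32) and AT4G33070, the pyruvate decarboxylase PDC1, 49.6-fold (5.63 ± 0.22). Loci with less known products rose as much, AT2G17850 (6.08 ± 0.26), AT4G10270 (5.70), AT5G10040 (5.64) and AT1G19530 (5.48). The deepest falls were in NCED4, a carotenoid cleavage dioxygenase (-4.29 ± 0.24), the cell wall enzymes XTH31 (-3.45 ± 0.18) and XTH6 (-2.94 ± 0.18), GLK2 (-2.99), the ferric reductase FRO6 (-2.96), AT4G38860 (-2.83), AT3G57010 (-2.79) and CYP706A6 (-2.74). In all, 9892 genes changed, 4817 up and 5075 down, with 1026 up and 697 down at least 2-fold. Rises made up 48.7% of the changes, and 33.7% with median centring.

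After 6 h, ADH1 stood 102-fold (6.68 ± 0.38) and HB1 99.2-fold (6.63 ± 0.32) above control in Columbia. NIP2;1 (6.44), FTM1, a stearoyl-ACP desaturase (6.39 ± 0.38), AT2G17850 (6.06), AT4G33070 (5.81), the sucrose synthase SUS4 (5.78 ± 0.20, 55-fold) and AT5G10040 (5.71) were next. The largest falls were in NCED4 (-4.76 ± 0.24), the light-harvesting genes LHCB2.1 (-3.40 ± 0.31) and LHCB2.2 (-3.33 ± 0.30), the ferric reductases FRO6 (-3.45) and FRO7 (-3.20), GLK2 (-3.22), the methionine sulfoxide reductase MSRB6 (-3.28) and XTH7 (-3.16). In all, 10305 genes changed, 4938 up and 5367 down, with 1022 up and 1009 down at least 2-fold. Rises made up 47.9% of the changes, and 37.6% with median centring.

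The core oxygen-deprivation genes, of which 36 were tested, rose almost without exception in Columbia: 35 at 1 h and all 36 at 3 h and 6 h, over all genes tested and adjusted over the list alone. Their median change was 2.93 at 1 h, 4.13 at 3 h and 4.34 at 6 h (adjusted p = 4.2e-44, 5.1e-37 and 2.7e-34). This call held with an estimated correlation (adjusted p = 0.0011, 0.0013 and 0.0017). Of 15 genes of sucrose breakdown, glycolysis and fermentation, 7 rose at 1 h, 9 at 3 h and 11 at 6 h, and 1 fell at 3 h and at 6 h, with medians of 0.20, 1.58 and 1.42 (adjusted p = 5.3e-04, 1.3e-05 and 6.3e-07). The list was not called with an estimated correlation, at adjusted p = 0.19, 0.11 and 0.079 with an estimated correlation. AlaAT1, an alanine aminotransferase (2.57 at 3 h), and the phosphofructokinase PFK6 (2.03 at 3 h) rose with ADH1, AT4G33070 and SUS4.

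Ethylene genes rose in Columbia, 9, 12 and 14 of the 16 tested at 1, 3 and 6 h, with 1 fall at 3 h and 1 at 6 h and medians of 0.37, 0.71 and 0.70. Those that rose most were ACO1, which makes ethylene (4.30 at 6 h), the synthase ACS7 (3.05 at 6 h), the receptors ETR2 (2.75 at 3 h) and ERS1 (1.38 at 3 h), and EBF2, which targets EIN3 for degradation (1.54 at 3 h). The list was called at each time (adjusted p = 4.9e-04, 2.3e-06 and 6.8e-06), though at adjusted p = 0.13, 0.053 and 0.063 with an estimated correlation. Dark-induced and sugar-starvation genes rose as well, 10, 12 and 10 of 12, with medians of 1.11, 1.99 and 1.25 (adjusted p = 1.2e-07, 4.0e-08 and 2.0e-04), and adjusted over the list alone 12, 12 and 10. The adjusted p was 0.10, 0.086 and 0.22 with an estimated correlation. BCAT-2, which acts on branched-chain amino acids (3.31 at 3 h), DIN11 (2.42), the glutamate dehydrogenase GDH2 (2.06) and the asparagine synthetase ASN1 (2.09 at 1 h) were among them.

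Defence genes rose early in Columbia. Of 31 innate immunity markers, 20 rose at 1 h and 23 at 3 h and 6 h, with 2 falls at 3 h and 1 at 6 h and medians of 0.87 at 1 h and 1.32 at 3 h (adjusted p = 1.2e-14, 1.5e-08 and 2.6e-08). This call was lost with the correlation estimated (adjusted p = 0.063, 0.14 and 0.15 with an estimated correlation). PHI-1 (4.18), the tetraspanin TET8 (2.89) and the MAP kinase MPK3 (2.78) rose at 1 h, and the ubiquitin ligase PUB22 by 2.78 at 6 h. In the WRKY family without WRKY22, 59 genes tested, 27 rose at 1 h, 37 at 3 h and 33 at 6 h while 1, 1 and 2 fell, with medians of 0.24, 0.39 and 0.46. WRKY40 (4.26), WRKY33 (3.52), WRKY18 (2.89) and WRKY46 (2.68) led at 1 h, and WRKY6 (2.71 at 3 h) and WRKY11 (2.77 at 6 h) later. The family was called at all times (adjusted p = 2.1e-08, 5.9e-09 and 2.6e-08), also with an estimated correlation (adjusted p = 0.0086, 0.0075 and 0.0086).

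Jasmonate genes rose at 1 h in Columbia, 12 of 17 with 1 fall (median 0.88, adjusted p = 1.9e-05, and adjusted p = 0.27 with an estimated correlation), led by the repressor genes JAZ7 (1.71) and JAZ10 (1.68) and the lipoxygenase LOX3 (1.67). At 3 h, 5 rose and 4 fell, and at 6 h 2 rose and 5 fell, without a call of the list. Of 13 reactive oxygen and mitochondrial stress markers, 5 rose at 1 h (adjusted p = 0.0041, and 0.24 as the adjusted p with an estimated correlation), among them the zinc finger gene STZ (3.74) and BCS1 (1.96). Their median was 0.04 at 1 h, so that the list rests on a few large rises, and it was not called at 3 h or 6 h. Heat shock genes rose in 5, 8 and 7 of 13 (medians 0.72, 0.92 and 0.91, adjusted p = 0.0081, 6.6e-04 and 0.0022, and adjusted p = 0.54, 0.39 and 0.47 with an estimated correlation). The small heat shock proteins HSP17.6A (4.16 ± 0.63 at 6 h), HSP17.4 (3.59 ± 0.58 at 3 h) and HSP17.6II (3.31 ± 0.63 at 3 h) varied between arrays, and without Columbia 1 h replicate 3 the list was not called at 1 h (adjusted p = 0.10).

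Photosynthesis and cell cycle genes fell in Columbia. Of 20 photosynthesis genes, 3 fell at 1 h, 11 at 3 h and 19 at 6 h and 0 rose, with medians of -0.12, -0.29 and -0.75. Besides LHCB2.1, the antenna gene LHCB6 fell by 2.06 at 6 h. Replicates varied widely, with list medians per array from -1.32 to 0.63 at 3 h and from -1.73 to -0.12 at 6 h. The list was called lower at each time (adjusted p = 0.049, 2.5e-04 and 1.6e-08), though at adjusted p = 0.67, 0.39 and 0.19 with an estimated correlation. The 1 h call ended without Columbia 1 h replicate 3 (adjusted p = 0.11) or replicate 4 (0.081), and at values of 0.05 or just above without some arrays of other groups. Of 19 genes of the cell cycle and DNA replication, 6 fell at 1 h, 15 at 3 h and 14 at 6 h and 0 rose, among them PCNA1 (-0.84), CDKB1;1 (-0.82) and CYCA1;1 (-0.80) at 6 h. The list was not called at 1 h but at 3 h (median -0.41, adjusted p = 2.1e-04) and 6 h (median -0.56, adjusted p = 1.8e-05), and at adjusted p = 0.24 and 0.19 with an estimated correlation.

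Other lists went both ways. Of 14 expansins and xyloglucan endotransglucosylases in Columbia, 5 rose and 6 fell at 1 h, 3 rose and 7 fell at 3 h, and 3 rose and 8 fell at 6 h, with TCH4 at 4.02 at 1 h beside the falls of XTH31 and XTH7. At 1 h their median was -0.16 while mean and test pointed up. Of 13 clock genes, 2 fell at 1 h, 6 rose and 4 fell at 3 h, and 4 rose and 4 fell at 6 h, with CCA1 (-2.08) and LHY (-1.18) lower and PRR5 (2.27 ± 0.87) and FKF1 (1.47) higher at 3 h. Since no time is given for the controls, hour of harvest and submergence cannot be told apart for these genes. Of 17 root-enriched markers, 8 fell and 2 rose at 6 h, among them PYK10 (-1.72) and CASP2 (-0.68) lower and PHO1 (0.83) higher, and IRT1 had fallen by 1.88 at 3 h. The ribosomal list held only the 6 tested genes that met its rule on names, so it does not stand for all cytosolic ribosomal proteins. Of these 6 genes 3 rose at 1 h, and 1 rose and 1 fell at 3 h and at 6 h. RPL18AA (1.28 at 6 h) was 1 of the genes whose probes gave opposite calls, and the rises of P40 (0.27) and PFL (0.26) at 1 h turned to -0.11 each with median centring. None of these 4 lists was called at any time in Columbia. With the replicate number as a block, expansins were called lower at 3 h and 6 h (adjusted p = 0.032 and 0.040).

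**Figure D2:**
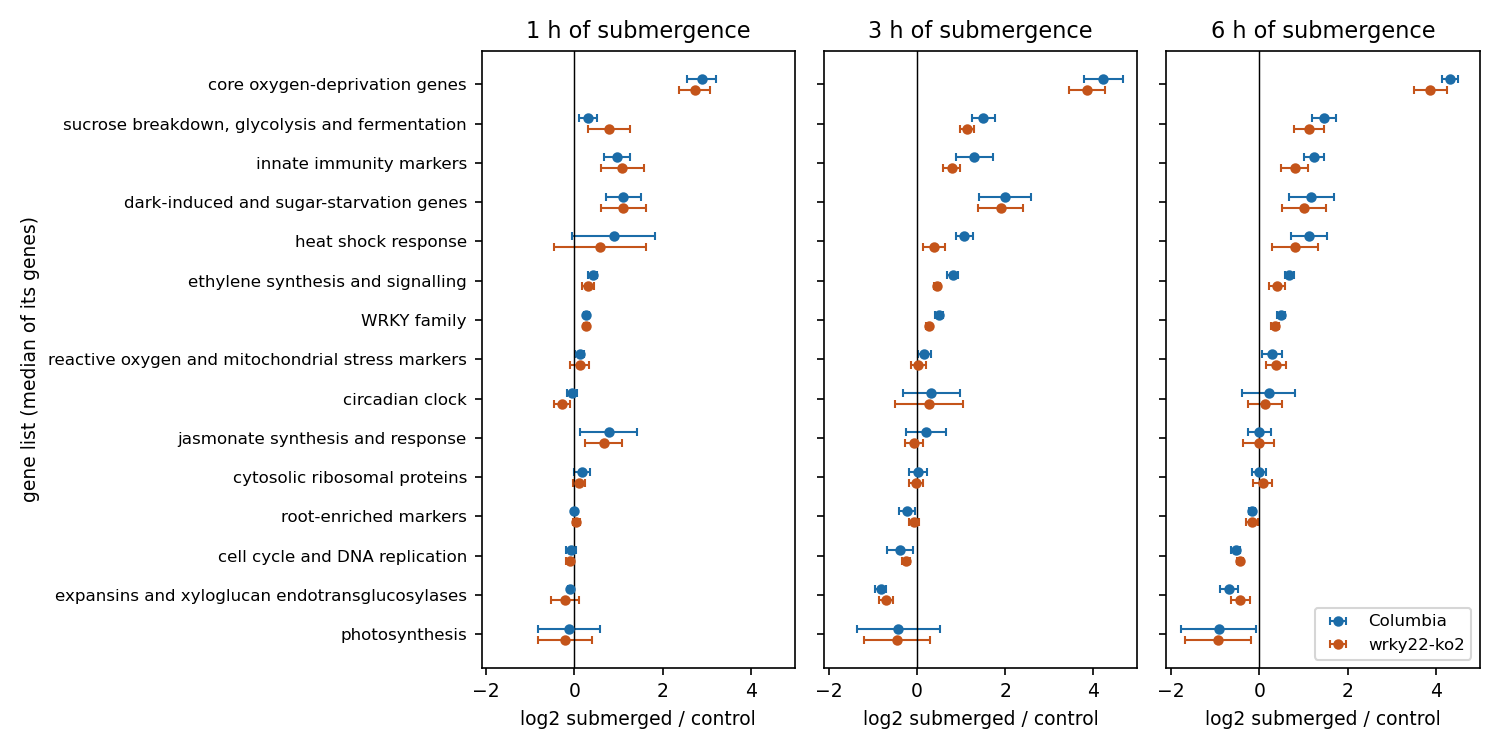
Median log2 ratio of submerged over control (x axis) of each of 15 gene lists at 1, 3 and 6 h, as the mean and SD of the medians of the 4 arrays of a group, Columbia in blue and wrky22-ko2 in orange. The core oxygen-deprivation genes lie highest, at 4.32 in Columbia and 3.88 in wrky22-ko2 at 6 h.

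In wrky22-ko2 the first hour brought rises in many of the genes named for Columbia. The largest were AT2G32200 (4.87 ± 0.33), AT1G33055 (4.75), AT4G10270 (4.69), CYP81F2 (4.63 ± 0.39), CML38 (4.34 ± 0.26), AT4G24110 (4.25), the cell wall enzyme gene XTR6 (4.14 ± 0.24) and SRO5 (4.12 ± 0.17). AT4G38860 (-2.76), GLK2 (-2.36), AT3G28040 (-2.12), GPRI1 (-2.11), G3Pp1, a glycerol-3-phosphate transporter gene (-1.99), the expansin EXPA8 (-1.98), NCED4 (-1.96) and BBX15 (-1.93) fell most. In all, 5748 genes changed, 2883 up and 2865 down, with 767 up and 132 down at least 2-fold. Rises made up 50.2% of the changes, and 39.4% with median centring.

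At 3 h in wrky22-ko2, ADH1 rose 50.5-fold (5.66 ± 0.38), HB1 by 5.39 ± 0.32 and SUS4 by 5.17 ± 0.20, followed by AT4G33070 (5.09), AT1G33055 (4.95), AT4G10270 (4.91), AT2G17850 (4.89) and AT4G27450 (4.86). NCED4 (-3.90 ± 0.24), XTH31 (-3.07), FRO6 (-2.87), GLK2 (-2.82), AT1G52100 (-2.82), the nicotianamine synthase NAS1 (-2.77), AT4G38860 (-2.76) and VTC2, an enzyme of ascorbate synthesis (-2.67), fell most. In all, 8168 genes changed, 3816 up and 4352 down, with 733 up and 520 down at least 2-fold. Rises made up 46.7%, and 32.0% with median centring.

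At 6 h in wrky22-ko2, HB1 stood 81.4-fold (6.35 ± 0.32) and ADH1 72.6-fold (6.18 ± 0.38) above control, and FTM1 (5.48), AT2G17850 (5.38), SUS4 (5.18), AT5G10040 (5.06), AT4G24110 (5.03) and AT4G10270 (5.03) rose next. Falls were led by LHCB2.2 (-3.27 ± 0.30) and LHCB2.1 (-3.21 ± 0.31), then SQP1, named as a squalene monooxygenase (-2.77), AOR (-2.71), CCB3, a factor for cytochrome assembly in chloroplasts (-2.70), CGLD27 (-2.69), AT1G52100 (-2.65) and TLL1 (-2.62). In all, 8702 genes changed, 4255 up and 4447 down, with 813 up and 747 down at least 2-fold. Rises made up 48.9%, and 27.7% with median centring. Without the arrays of replicates 1 and 2, whose signal over background was the highest or lowest of all, 5701 genes were called.

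**Figure D3:**
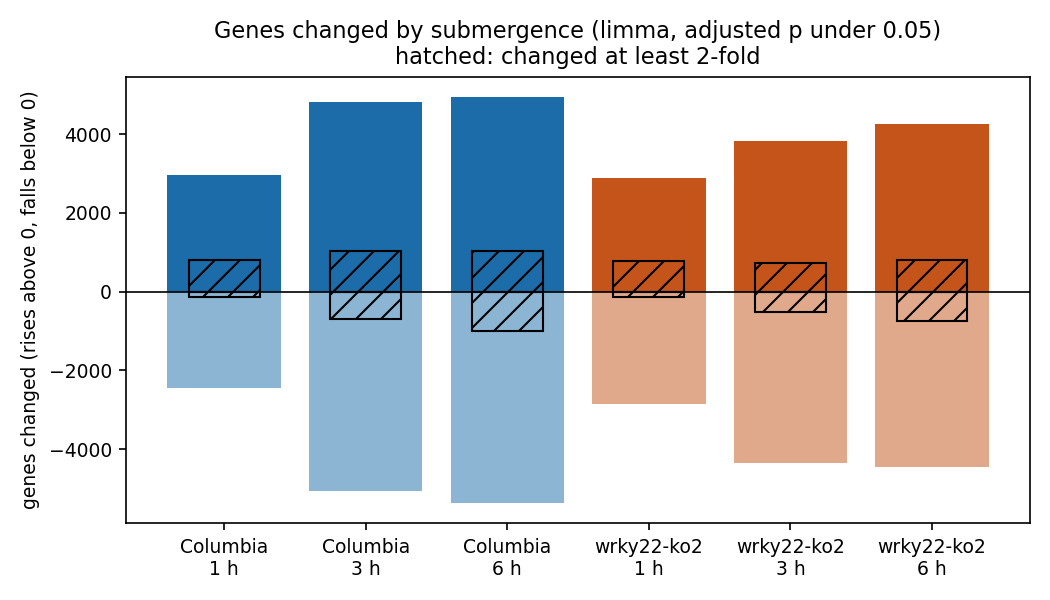
Number of genes that rose or fell (adjusted p under 0.05, limma) in each of the 6 comparisons of submerged with control seedlings, rises above 0 and falls below 0 on the y axis, with the hatched part changed at least 2-fold. Numbers rose from 5426 at 1 h to 10305 at 6 h in Columbia and from 5748 to 8702 in wrky22-ko2.

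Lists that were called at the same time in both genotypes were called in the same direction. Of the 36 core oxygen-deprivation genes, 35 rose at 1 h and 36 at 3 h and 6 h (medians 2.60, 3.85 and 3.93, adjusted p = 5.0e-42, 1.0e-43 and 2.0e-38, and adjusted p = 0.0011, 0.0011 and 0.0013 with an estimated correlation). WRKY family members rose in 27, 27 and 31 of 59 (medians 0.21, 0.20 and 0.32, adjusted p = 0.011, 0.016 and 0.016 with an estimated correlation). Rises were called for 7, 9 and 11 of the 15 glycolysis genes, with 3 falls at 3 h and 2 at 6 h, PPDK rising by 2.33 at 3 h. They were called for 21, 19 and 23 of the 31 immunity markers, 7, 10 and 10 of the 16 ethylene genes and 10, 10 and 9 of the 12 dark-induced genes, such as MCCA (2.28) and SEN1 (2.18) at 3 h. These 4 lists were called at each time, with adjusted p between 4.3e-13 and 0.0015, and between 0.079 and 0.24 as adjusted p with an estimated correlation.

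Among the other lists in wrky22-ko2, jasmonate genes were called at 1 h only (11 of 17 rose, adjusted p = 2.8e-04, and adjusted p = 0.36 with an estimated correlation), 2 rose and 5 fell at 3 h, and LOX2 fell by 1.99 at 6 h. Reactive oxygen markers were called at 1 h (5 of 13 rose, adjusted p = 0.0075) and 6 h (6 rose, adjusted p = 0.0069), with UGT74E2 at 2.90 and the oxidase RBOHD at 2.53 at 1 h and RHL41 at 2.33 at 6 h, and adjusted p = 0.27 with an estimated correlation at both times. Heat shock genes rose in 2, 5 and 7 of 13, and the list was called at 6 h (adjusted p = 0.0053, and adjusted p = 0.52 with an estimated correlation). With the replicate block heat shock genes were also called at 1 h and 3 h (adjusted p = 0.012 and 0.044), and at 1 h also without wrky22-ko2 1 h replicate 1 (0.011). Photosynthesis genes fell in 3, 12 and 19 of 20 (medians -0.19, -0.33 and -0.79, adjusted p = 0.0047, 2.9e-05 and 6.7e-10, and adjusted p = 0.54, 0.33 and 0.15 with an estimated correlation), with PRK, an enzyme of the Calvin cycle (-2.45), PSAD-1 (-1.92), LHCB3 (-1.76) and NPQ4 (-1.54) at 6 h. Cell cycle genes fell in 9 of 19 at 3 h, and in 14 at 6 h (adjusted p = 0.0037 and 5.4e-05, and adjusted p = 0.37 and 0.21 with an estimated correlation). The expansin, clock, root and ribosomal lists were not called, apart from expansins at 3 h with the replicate block (adjusted p = 0.045), and the expansin list again had a negative median (-0.38) with mean and test pointing up at 1 h. XTH24 rose by 2.42 at 3 h, and among root markers NRT2:1 rose by 1.21 and SHV2 fell by 0.64 at 6 h.

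Most genes that changed in one genotype changed the same way in the other. At 1 h, 2350 genes rose in both, where independent calls would give 421, and 1952 fell in both, against 347. At 3 h, 3401 rose (905 if independent) and 3780 fell (1088) in both, and at 6 h 3775 rose and 3943 fell in both. The calls of both genotypes came from 1 fit with a shared spread, and arrays of the same replicate number deviated together. Independent calls are thus only a reference and not the overlap that chance would give. Opposite calls were made for 0 genes at 1 h, for AT2G16930 and AT2G24400 at 3 h and for AT5G24260 and AT5G54790 at 6 h, which are named although chosen after their values were seen. Across genes, which are not independent replicates, the changes of the genotypes correlated with r of 0.964, 0.950 and 0.961. The slope of wrky22-ko2 on Columbia was 0.984 at 1 h, 0.851 at 3 h and 0.870 at 6 h.

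The difference between the genotypes in their response was tested to find genes that depend on the WRKY22 line. At 1 h, WRKY22 was the only gene called. The next by p, none of which passed (adjusted p = 1), included AT5G24640 (0.86 ± 0.22), CYP96A9 (mostly dim in control channels), AT3G01345 (0.71, dim in both channels of wrky22-ko2), AT5G44680 (0.46) and AT5G22320 (-0.45), and 277 genes had an unadjusted p under 0.05. The ratios of the 2 genotypes did not overlap for 0.97% of all genes at 1 h, where chance gives 2.86% for independent arrays, which those of the same replicate number were not at any of the times.

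At 3 h, most of the genes called were lower in wrky22-ko2. AT2G36690, an oxygenase-like gene (difference -2.27 ± 0.35), MLO12, a gene of the powdery mildew susceptibility family (-2.17 ± 0.44), AT2G39518 (-1.91 ± 0.36), WRKY49 (-1.89 ± 0.30), AT5G44910 (-1.71) and AT5G48430 (-1.63) were lower. Also lower were the chloroplast small heat shock protein HSP21, FRK1, a receptor kinase induced by flagellin, and AT1G51820, with a size left open by control channels not above background. HSP21 had risen at least 5.17-fold in Columbia and at least 1.73-fold in wrky22-ko2, and FRK1 at least 3.94-fold in Columbia, while in wrky22-ko2 its change was not called (adjusted p = 0.43). Higher were AT1G26761 (0.95 ± 0.19), AT3G26960 (0.94 ± 0.17), the B-box gene BBX18 (0.92), LGO, a cell cycle inhibitor (0.89), AT3G05180 (0.85), AT3G06145 (0.82), AT3G06750 (0.81), AT2G40460 (0.79), AT3G48460 (0.73) and, with dim submerged channels, AT5G06790. In all, 62 genes were called, 15 higher and 47 lower in wrky22-ko2, 25 of them lower by at least 2-fold, and for 55 of the 62 the 4 and 4 ratios did not overlap (2.62% of all genes, 2.86% by chance for independent arrays).

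The count at 3 h depended on the fit. With the replicate number as a block it was 195, and 458 with the block within each time, both including all 62 genes. With the Columbia changes multiplied by the slope of 0.851 and missing ratios replaced by fitted values, 5 genes were called. Scale normalization gave 3, or 104 together with the block within each time, and single arrays left out gave from 6 (Columbia 3 h replicate 3) to 148 (Columbia 3 h replicate 1). The median ratio of wrky22-ko2 to Columbia changes was 0.878 over 874 genes with large rises in the genotypes together. It was 0.909 over 604 genes with large falls. Both lie above the slope, so the scaling may lower many Columbia changes too far.

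**Figure D4:**
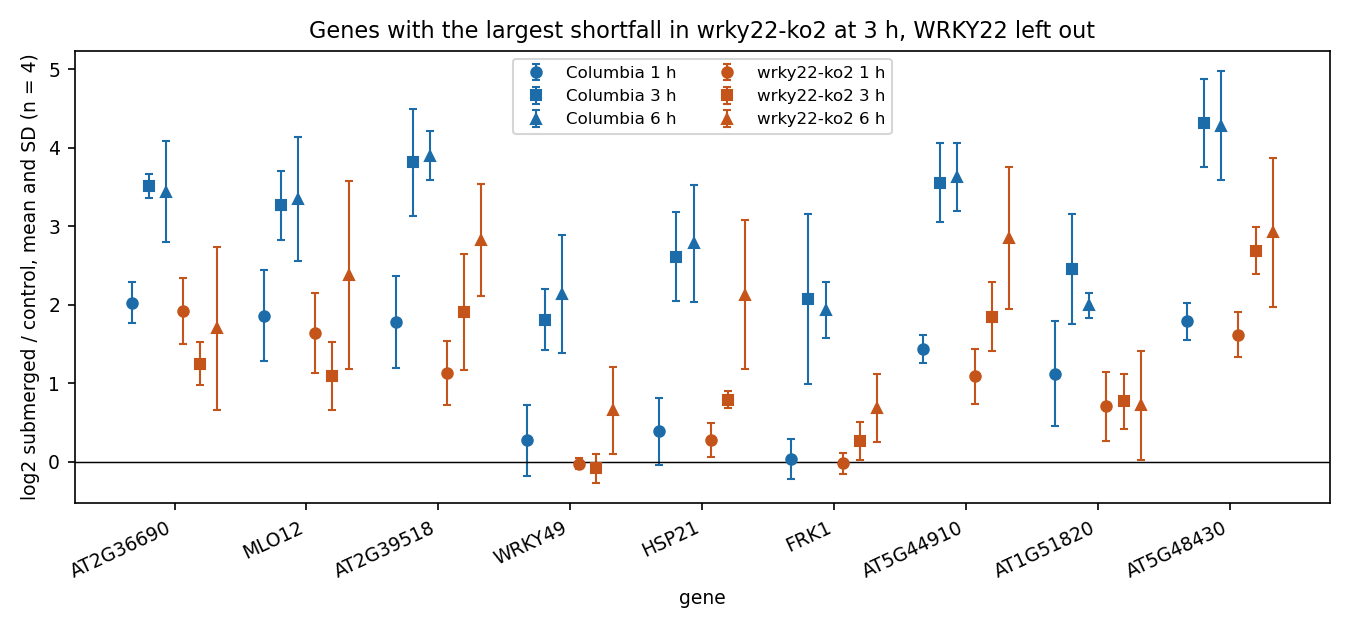
Log2 ratio of submerged over control (y axis, mean and SD of 4 arrays) at 1, 3 and 6 h in both genotypes, for the 9 named genes lower in wrky22-ko2 at 3 h, WRKY22 left out. At 3 h the means lie lower in wrky22-ko2 for all 9 genes, by -2.27 for AT2G36690, and those of HSP21, FRK1 and AT1G51820 rest on dim control channels.

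At 6 h, the genes called lower in wrky22-ko2 were WRKY22, OPT1, an oligopeptide transporter (-1.50 ± 0.20, adjusted p = 0.0024), the sucrose synthase SUS2 (adjusted p = 0.013, its size open for control channels not above background), the nudix hydrolase NUDX25 (-1.08 ± 0.17), PSK1, a phytosulfokine precursor (-1.02 ± 0.17), the centromere protein CENP-C (-0.90) and AT4G17940 (-0.83). AT2G01610, dim in submerged channels of Columbia, AT4G10280 (0.64) and AT2G25625 (0.75, whose ratios overlapped and which is named outside the rule) were higher. SUS2 had risen at least 2.73-fold in Columbia and at least 1.22-fold in wrky22-ko2. In all, 10 genes were called, of which 9 did not overlap (2.83% of all genes, 2.86% by chance for independent arrays), and 1494 had an unadjusted p under 0.05. With the Columbia changes multiplied by the slope of 0.870, limma called 0 genes (935 at an unadjusted p under 0.05), with WRKY22 at -2.24 ± 0.37 (adjusted p = 0.052). The median ratio of wrky22-ko2 to Columbia changes was 0.881 for large rises and 0.887 for large falls, above this slope. The count was 50 with the replicate block and 226 with the block within each time, both including all 10 genes, 2 with scale normalization, and from 2 to 15 with single arrays left out, the lowest without Columbia 6 h replicate 3 or wrky22-ko2 6 h replicate 3 or 4.

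Several gene lists that rose in Columbia responded less in wrky22-ko2 at 3 h and 6 h. The WRKY family was lower by a median of -0.17 at 3 h (adjusted p = 2.1e-08) and -0.11 at 6 h (adjusted p = 1.3e-05), and these calls held with an estimated correlation (adjusted p = 0.0086 and 0.043), with 1 member called at 3 h and 11 adjusted over the list alone. The core oxygen-deprivation genes were lower by -0.34 at 3 h (adjusted p = 6.3e-07, and adjusted p = 0.15 with an estimated correlation), with AT5G10040 (-1.23) and PFK6 (-0.62) called over all genes and 6 adjusted over the list alone, and by -0.40 at 6 h (adjusted p = 2.0e-08, and adjusted p = 0.11 with an estimated correlation). Heat shock genes were lower by -0.92 at 3 h (adjusted p = 2.2e-07, and adjusted p = 0.19 with an estimated correlation), with HSP21 called and 4 adjusted over the list alone, and by -0.55 at 6 h without a call (adjusted p = 0.052), where the replicate block gave 0.0033 and the block within each time 1.6e-04. Immunity markers (-0.28 and -0.24), ethylene genes (-0.22 and -0.19) and glycolysis genes (-0.24 and -0.31) were lower at 3 h and 6 h, with adjusted p = 4.2e-06 and 3.5e-04, 5.7e-05 and 0.0012, and 7.7e-05 and 1.5e-04. With the correlation estimated these were not called (adjusted p = 0.22 and 0.36, 0.084 and 0.15, and 0.14 and 0.15 with an estimated correlation), and the immunity call at 6 h ended without wrky22-ko2 6 h replicate 4 (adjusted p = 0.12). With the Columbia changes multiplied by the slope, list tests were adjusted over the 15 lists of a time. Then 4 of 8 lists stayed called lower at 3 h and 1 of 5, the WRKY family, at 6 h, while the core genes turned called higher (adjusted p = 3.0e-05 and 0.028, and adjusted p = 0.37 and 0.82 with an estimated correlation). The WRKY family was then no longer called at adjusted p = 0.26 and 0.64 with an estimated correlation.

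Other list differences were small or rested on single arrays. At 3 h, jasmonate (-0.25, adjusted p = 0.0077) and reactive oxygen markers (-0.07, adjusted p = 0.025) were lower, cell cycle genes were higher, that is, fell less (0.12, adjusted p = 0.0041), and root markers were higher (0.11, adjusted p = 0.0093). With an estimated correlation none was called (adjusted p = 0.54, 0.36, 0.38 and 0.13 with an estimated correlation). Single arrays of 3 h ended each of these calls: Columbia replicate 4 (adjusted p = 0.85) or wrky22-ko2 replicate 2 (0.078) for jasmonate, Columbia replicate 3 (0.33) or wrky22-ko2 replicate 1 (0.17) for cell cycle, Columbia replicate 1 (0.14) or wrky22-ko2 replicate 2 (0.098) for root markers, and Columbia replicates 2, 3 or 4 (0.11, 0.12 and 0.052) or wrky22-ko2 replicates 1 or 4 (0.078 and 0.11) for reactive oxygen. At 1 h, core genes (-0.10, adjusted p = 0.043), heat shock genes (-0.21, 0.037) and jasmonate genes (-0.10, 0.031) were called lower, each lost without Columbia 1 h replicate 3 (adjusted p = 0.82, 0.88 and 0.10) or 4 (0.16, 0.40 and 0.28) or wrky22-ko2 1 h replicate 1 (0.15, 0.93 and 0.055), 2 (0.097, 0.28 and 0.16) or 4 (0.30, 0.29 and 0.069). They were at adjusted p = 0.58, 0.63 and 0.62 with an estimated correlation. Core genes were not called without Columbia 1 h replicate 2 either (0.059). At 6 h, expansins and xyloglucan endotransglucosylases were higher (0.27, adjusted p = 0.0041, and adjusted p = 0.084 with an estimated correlation), which ended without the doubted wrky22-ko2 arrays (adjusted p = 0.10). With the block within each time, this list was also called higher at 1 h (adjusted p = 0.024) and 3 h (0.047), dark-induced genes lower at 6 h (0.0034, and 0.023 with the replicate block over all times) and reactive oxygen markers higher at 6 h (0.021). Photosynthesis, clock and ribosomal lists were not called at any time over all arrays. Photosynthesis was called lower at 1 h without Columbia 1 h replicate 3 (adjusted p = 0.020) and at 3 h higher without Columbia 3 h replicate 1 (0.025) and lower without replicate 2 (0.033). Ribosomal proteins were called lower at 1 h without wrky22-ko2 1 h replicate 3 (0.047).

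Averaged over the 3 times, the response of wrky22-ko2 was lower for WRKY22 (-3.39), the late-rising AT2G17740 (-1.55 ± 0.29), AT2G36690 (-1.37), WRKY49 (-1.22), AT2G39518 (-1.21), AT1G51620 (-1.20), MLO12 (-1.12) and AT5G48430 (-1.01), and for AT1G51820 and FRK1, whose size is open for dim control channels. It was higher for SAG29, a sugar transporter gene (0.73 ± 0.17), the iron transporter IRT1 (0.67 ± 0.12), BBX30 (size open for dim submerged channels), AT3G01345 (0.61), the chloroplast NADH dehydrogenase subunit NdhT (0.58), AT4G24700 (0.56), AT3G56290 (0.51), NAS2 (0.51), AT2G40460 (0.49) and AT1G61795 (0.49), n = 12 arrays per genotype. AT3G01345 was dim in both channels of wrky22-ko2 (mean log2 signal 7.10 in each). Its difference rests on the fall in Columbia, from 11.76 in control to 11.16 in submerged channels. In all, 439 genes were called, 177 higher and 262 lower, and 10 lower at least 2-fold. The slide correlation of this fit was negative (-0.119), which narrows the standard errors of a comparison between slides. Far fewer genes were called without the slide block. The count was 22 with median centring, 109 with scale normalization, 77 as the mean contrast of the 6 groups and 983 with scan day as the block. It was 3 with the ratios averaged per replicate number (WRKY22 alone of the genes named here), and from 156 (without Columbia 3 h replicate 2) to 1149 (without Columbia 1 h replicate 1) with single arrays left out.

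From 1 h to 6 h in Columbia, FTM1 rose by a further 4.62 ± 0.53, AT2G17740 by 3.94, ADH1 by 3.77 ± 0.53, AT5G01740 by 3.76 and AT3G03270, listed as HRU1, by 3.22 ± 0.17. AT3G29970, AT3G03670 and AT2G29870 also rose, but their control channels at 1 h or 6 h were not above background, so that the size is open. AT3G55840 (-3.78), the purine permease gene PUP18 (-3.74), BT5 (-3.24), LHCB2.1 (-3.18), LHCB2.2 (-3.08), AT1G56060 (-2.96), NCED4 (-2.94) and AT1G02660 (-2.83) fell, and WRKY22 by 1.08 (adjusted p = 0.034). In all, 5434 genes differed between the times, 2204 up and 3230 down, with 403 up and 797 down at least 2-fold. Controls of the times were not told apart in the labels, and 40.6% of the changes were rises, against 67.3% with median centring.

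In wrky22-ko2, FTM1 (4.05 ± 0.53), ADH1 (3.76 ± 0.53), HB1 (3.28), AT5G01740 (3.19), AT3G03270 (2.77 ± 0.17) and the mitochondrial small heat shock protein HSP23.6-MITO (2.58) rose from 1 h to 6 h, as did AT3G03670 and AT3G29970, whose control channels at 1 h were again not above background. AT3G55840 (-3.87), PUP18 (-3.28), LHCB2.2 (-3.07), LHCB2.1 (-2.96), BT5 (-2.93), AT1G02660 (-2.81), GDPD2 (-2.68) and GAT1_2.1 (-2.68) fell, and WRKY22 did not pass the test (0.10 ± 0.37, adjusted p = 0.89). In all, 3691 genes differed, 1432 up and 2259 down, with 249 up and 563 down at least 2-fold. Rises made up 38.8%, and 14.9% with median centring, and 2206 genes were called without the dye term.

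Without submergence, a few genes stood far apart between the genotypes. AT3G01345 was lower in the control channels of wrky22-ko2 (-4.66 ± 0.14), where it was well above background on 10 of 12 arrays, with log2 signals of 7.10 ± 0.29 (SD, n = 12) against 11.76 ± 0.27 in Columbia. MRD1 (-2.60 ± 0.15), AT5G15360 (-1.99 ± 0.11, on 9 of 12 arrays), AT2G07698 (-1.85 ± 0.11), AT5G03090 (-0.90), AT4G04745 (-0.70), AT1G01170 (-0.66) and AT5G17070 (-0.58) were lower too. Besides WRKY22, CCMH, a factor of cytochrome c maturation (1.53 ± 0.30), RLK (AT2G37710), AT5G25550 (1.48), WRKY55 (1.37), AT1G24405 (1.16), AT1G56233 (1.14) and AT4G25920 (1.12, adjusted p = 0.051 with the replicate block) were higher. Of these higher genes, only WRKY22 and WRKY55 had array values that did not overlap between the genotypes. CCMH, for example, had an SD of 0.78 in wrky22-ko2 and 0.40 in Columbia. Among the lower genes, AT4G04745, AT1G01170 and AT5G17070 overlapped. In all, 112 genes were called, 73 higher and 39 lower in wrky22-ko2, 16 of them at least 2-fold. The channels come from different slides, and the count was 3036 without the slide block, 1104 with scan day as the block, 727 with the channels averaged per replicate number and from 51 (without Columbia 6 h replicate 1) to 266 (without wrky22-ko2 6 h replicate 2) with single arrays left out.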

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

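Among the tests below, those of the WRKY22 control signal, of the genes low in wrky22-ko2 control channels and of the splits of averaged values were chosen after the result was seen.

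The higher WRKY22 signal in the control channels of wrky22-ko2 (4.44-fold) was weighed first. An exchange of single arrays would put arrays of each genotype on the other side of the midpoint of the genotype means, and 0 arrays lay there, whereas an exchange of the labels on all arrays stays open, since WRKY22 differed by 2.15 in the control and by -1.24 in the submerged channels and neither labelling puts wrky22-ko2 lower in both. A general shift of the control channels would move other genes too, but the median difference over all tested genes was -0.0233, against 2.15 for WRKY22. Slides that vary apart from genotype would tend to give overlapping slide means. The gap between the genotypes' slide means was 1.745, larger than the widest range within a genotype of 0.59. A shift shared by all slides of a genotype would also leave a gap. A transcript that the insertion changes or partly leaves in place may underlie the signal, which is a hypothesis not tested here, since the probe position is not known and genotype and scan day cannot be separated.

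AT3G01345, MRD1, AT5G15360 and AT2G07698 were far lower in the control channels of wrky22-ko2. If the seed lines differ whatever the treatment, submerged channels should differ by nearly as much, and the ratio of the submerged to the control difference was 0.870 to 1.01 over the 4 genes. A shift between the slides of the genotypes would give such ratios too, since both channels of an array share a slide. Slides that vary apart from genotype would tend to give overlapping slide means. The lowest gap between the genotypes' slide means was instead 1.69, above the widest range within a genotype of 0.51. The 4 genes were picked for large differences, which favours such a gap. No scan day held both genotypes, so a shift between their slides cannot be told from a difference of the lines. A candidate explanation is a difference between the seed lines, in these genes or in their regulation, which need not involve the WRKY22 insertion.

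The smaller response of induced lists in wrky22-ko2 at 3 h was weighed last. If all ratios of that slide were compressed by 1 factor (slope 0.851), scaling the Columbia changes by it should end the list differences. Adjusted over the 15 lists of a time, 4 of the 8 lists called lower stayed lower (heat shock genes, WRKY family, immunity and jasmonate genes). None of them was called with an estimated correlation. The core oxygen-deprivation genes turned higher (adjusted p = 3.0e-05, and adjusted p = 0.37 with an estimated correlation). The slope lay below the median ratio of wrky22-ko2 to Columbia changes for large rises (0.878) and large falls (0.909), so it may scale many changes too far. If 1 array were the cause, leaving it out should end at least 4 of the 8 calls, and if not, no array should end more than 1. The most that any array ended was 2, between these limits, so a single array as the cause stays open. A slide-wide compression may thus account for part of the differences, and compression and a weaker response of the line cannot be told apart, since only 1 slide holds each group. After the scaling, 5 genes remained called at 3 h: WRKY22, NUDX25, OPT1, RBP47C' and AT4G00250.

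The response differed between the genotypes for 1 gene at 1 h, 62 at 3 h, 10 at 6 h and 439 in the mean of the times, and between 6 h and 1 h for 5434 genes in Columbia and 3691 in wrky22-ko2. List medians differed at 1 h by -0.10 (core oxygen-deprivation genes), -0.21 (heat shock) and -0.10 (jasmonate). At 3 h they differed by -0.92 (heat shock), -0.34 (core), -0.28 (immunity), -0.25 (jasmonate), -0.24 (glycolysis), -0.22 (ethylene), -0.17 (WRKY family), -0.0724 (reactive oxygen), 0.12 (cell cycle) and 0.11 (root markers). At 6 h they differed by -0.40 (core), -0.31 (glycolysis), -0.24 (immunity), -0.19 (ethylene), -0.11 (WRKY family) and 0.27 (expansins and xyloglucan endotransglucosylases). With the Columbia changes multiplied by the slope, 0 of 3 lists stayed called lower at 1 h (slope 0.984) and 1 of 5 at 6 h (0.870). This was the WRKY family (adjusted p = 0.038, and adjusted p = 0.64 with an estimated correlation). At 6 h the core genes turned higher (adjusted p = 0.028, and adjusted p = 0.82 with an estimated correlation).

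Other splits of the arrays were fitted for each count. For the submergence effects, turning arrays of a group around gives 8 splits, too few for a share under 0.05, and the real count and the highest other were 5426 and 5, 9892 and 1765, and 10305 and 8 in Columbia, and 5748 and 83, 8168 and 84, and 8702 and 708 in wrky22-ko2, with 1 split, the real one, as large each. For the counts of differences between genotypes, chance was not excluded: 3 of 35 splits gave at least 1 gene at 1 h (highest other 9), and 2 of 35 at least 62 at 3 h (highest other 476) and at least 10 at 6 h (highest other 102). Such counts do not weigh the size of the difference of a single gene, such as WRKY22 at 1 h. The splits with 476 and 102 genes set replicates 1 and 4 of both genotypes against replicates 2 and 3, which points to a structure of the samples by replicate number, and the blocked counts at 3 h and 6 h were 195 and 50. Among the 8 splits that part all 4 pairs of the same number, only the real one was as large at each time, with a highest other of 0. For the mean difference 1 of 100 splits was as large (406 genes with a correlation from fewer genes, highest other 133), but these splits take the arrays as independent, and with the ratios averaged per number 2 of 34 were (3 genes, highest other 740), so that chance was not excluded. Of the 8 splits of these averages that part all pairs, only the real one was as large (highest other 0). These 8 are too few for a share under 0.05. For 6 h against 1 h, 1 of 35 splits was as large in Columbia (5434 genes, highest other 1) and in wrky22-ko2 (3691, highest other 14). The numbers pair the arrays in Columbia and the control channels in wrky22-ko2, and only 8 splits part all pairs, too few for a share under 0.05. For the control channels 2 of 100 splits were as large (79 genes, highest other 737), which again takes channels as independent although those of a number deviate together. With the channels averaged per number, 1 of 34 splits, the real one, was as large (727 genes, highest other 576), but the numbers also pair these averages across the genotypes, and the 8 splits that part all pairs are too few for a share under 0.05. The splits with 740 and 576 genes again set replicates 1 and 4 against 2 and 3, which points to a structure by replicate number.

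Single arrays stood apart from the other 3 of their group in 16 of 239 sets, or 6.70%, where chance gives about 1 in 20. Replicate 1 held 12 of these 16. The median green signal was 113 in wrky22-ko2 1 h replicate 4 (others 142 to 147) and 179 in wrky22-ko2 6 h replicate 1 (92 to 104). The WRKY22 control signal was 9.16 in Columbia 1 h replicate 1 (7.82 to 8.02). In Columbia 1 h replicate 1, AT3G55840 was at 2.65 (5.12 to 5.45) and GPRI1 at -1.36 (-2.79 to -2.56). In Columbia 3 h replicate 1, XTH31 was at -3.12 (-3.59 to -3.54) and AT4G38860 at -1.76 (-3.31 to -3.08), and in Columbia 6 h replicate 1 FTM1 was at 4.82 (6.71 to 7.08). In wrky22-ko2 replicate 1, GLK2 was at -0.63 (-3.06 to -2.83) and GPRI1 at -1.18 (-2.51 to -2.35) at 1 h, NAS1 at -3.36 (-2.63 to -2.50) at 3 h, and CCB3 at -2.01 (-2.95 to -2.89) and the ethylene list median at 0.69 (0.30 to 0.32) at 6 h. At 6 h in wrky22-ko2, the expansin list median was -0.12 in replicate 2 (-0.56 to -0.50), the root list median -0.37 in replicate 4 (-0.12 to -0.08) and HB1 7.23 in replicate 3 (5.94 to 6.13).

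Probes that match no current gene name changed too, out of 5031 tested apart from the comparisons of the report: 625, 1451 and 1542 at 1, 3 and 6 h in Columbia, 700, 1152 and 1193 in wrky22-ko2, and 3 at 3 h and 6 at 6 h in the difference between the genotypes.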

How the results depend on the processing

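Chosen after the results were seen were the replicate block within each time, scan day as a block, the averaged control channels and ratios, leaving out 2 doubted arrays of wrky22-ko2 at 6 h, and for the gene lists also the replicate block and leaving out each array.

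Directions of named genes held in nearly all settings, while counts of genes that differ between the genotypes did not. Over 283 pairs of a named gene and a result, 6361 values were computed: 5825 kept direction and call or lack of one, 530 kept the direction without a call, and 6 turned. Of these values, 2144 came from leaving out single arrays. Most named genes were picked for large called changes on these same arrays, so refits could hardly turn them. The kept directions are thus no independent check. WRKY22 kept direction and call in its Columbia rise at each time and in its difference at 1 h and 3 h, from -4.51 to -3.55 and from -3.98 to -2.89. At 6 h its difference was -3.09 to -2.16, not called (adjusted p = 0.053) with only the compared groups. P40 and PFL turned at 1 h in Columbia with median centring (-0.11 and -0.11). The uncalled change of WRKY22 from 1 h to 6 h in wrky22-ko2 turned with median centring (-0.0925) and without wrky22-ko2 1 h replicate 2 (-0.0072), 6 h replicate 3 (-0.0081) or 6 h replicate 4 (-0.091), with a highest value of 0.40 without 6 h replicate 2. Dim genes were limited by signal over background, since 43.5% to 72.6% of spots per array were well above it in red, and the control channel count rose from 112 to 366 without a filter on dim probes. The authors' values hold ratios alone and were not run for the control channels. The cause was not tested for any change given in this part, except that a 2-fold limit calls fewer genes by construction.

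A change of at least 2-fold was met by 947, 1723 and 2031 genes in Columbia at 1, 3 and 6 h (of 5426, 9892 and 10305), by 899, 1253 and 1560 in wrky22-ko2 (of 5748, 8168 and 8702), by 25 in the difference at 3 h (of 62), 5 at 6 h (of 10), 10 in the mean difference (of 439), 1200 from 1 h to 6 h in Columbia (of 5434), 812 in wrky22-ko2 (of 3691) and 16 in the control channels (of 112).

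Median centring gave 9584 at 1 h in Columbia (3791 shared), and 36, 2 and 22 in the differences at 3 h, at 6 h and in the mean. In the same order, scale normalization gave 3, 2 and 109, processed signals 15, 3 and 88, and the authors' values 17, 3 and 78. The differences at 3 h and 6 h had 13 and 3 genes without the dye term, 15 and 0 with only the groups compared, 116 and 27 with array weights, 195 and 50 with the replicate block, 458 and 226 with the block within each time, and 104 (41 shared) and 26 (7 shared) with that block after scale normalization. No background correction gave 40 at 3 h and the stricter filter 5 at 6 h. The mean difference had 41 genes without the slide block, 77 as the mean contrast of the 6 groups, 3 with ratios averaged per number and 983 with scan day as the block. Without the dye term, 2206 genes changed from 1 h to 6 h in wrky22-ko2. The control channels gave 63 without the dye term, 315 with the mean of a gene's probes, 186 with array weights, 3036 without the slide block, 1104 with scan day as the block, 727 averaged per number and 4553 so averaged with a replicate block. Without the 2 doubted arrays there were 5701 genes at 6 h in wrky22-ko2, 27 in the difference at 6 h, 197 in the mean difference and 207 in the control channels.

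Of 74 list calls, 14 were made with an estimated correlation, and fry gave 74 with 14 lost and 14 gained. Lost were photosynthesis at 1 h in both genotypes, the 3 list differences at 1 h, heat shock (adjusted p = 0.097), immunity (0.11), jasmonate, cell cycle, reactive oxygen and root genes in the difference at 3 h, and ethylene (0.061), immunity (0.25) and glycolysis genes (0.060) at 6 h. Gained were expansins at each time and root markers at 3 h and 6 h in both genotypes, reactive oxygen markers at 3 h and 6 h and ribosomal proteins at 1 h in Columbia, and ribosomal proteins at 6 h in wrky22-ko2. No filter added expansins (0.038 and 0.042) at 3 h and 6 h and root markers (0.042) at 3 h in Columbia, and no background correction added dark-induced genes to the difference at 6 h (0.049) and lost heat shock genes at 1 h (0.10). Photosynthesis at 1 h in Columbia was at 0.052 without the doubted arrays. The replicate block changed no call of a list or named gene beyond those given in the report. Numbers did not pair the ratios of wrky22-ko2 at 1 h and 6 h (correlations from -0.129 to 0.307, 1 of 4 highest with its own number), though they did its control channels (0.258 to 0.614, 4 of 4), and the replicate block gave 4874 changes.

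Leaving out 1 array at a time gave 3851 to 4492, 8057 to 9229 and 8947 to 9230 genes at 1, 3 and 6 h in Columbia, 4344 to 4870, 6708 to 7187 and 7430 to 7765 in wrky22-ko2, 1 to 1, 6 to 148 and 2 to 15 in the differences, 156 to 1149 in the mean difference, 4401 to 5107 and 2934 to 3278 from 1 h to 6 h in Columbia and wrky22-ko2, 51 to 266 in the control channels, and 70 to 78 list calls. At 3 h all 8 arrays moved the count over 1.5 times, in Columbia replicates 1 to 4 to 148, 18, 6 and 39 and in wrky22-ko2 to 16, 40, 38 and 11, as did 15 of 24 in the mean difference and 5 of 24 in the control channels. Single arrays left out also made list calls: in the differences immunity lower at 1 h (0.0098), dark-induced genes lower at 3 h (0.0077), and at 6 h heat shock and dark-induced genes lower (lowest 8.0e-04 and 0.0038), jasmonate lower (0.049) and cell cycle and reactive oxygen genes higher (lowest 0.032 and 0.025), and in Columbia cell cycle at 1 h (0.047), expansins and root markers at 3 h (lowest 0.034 and 0.036) and expansins and reactive oxygen markers at 6 h (lowest 0.045 and 0.034).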

Other observations

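Besides WRKY22, OPT1, NUDX25 and PSK1 were called lower in the response of wrky22-ko2 at both 3 h and 6 h, a group picked after the values were seen. AT2G01610, dim in submerged channels of Columbia at 6 h, was called higher at both. Ratios of the same replicate number deviated together at 3 h and 6 h (0.231 to 0.479 in Columbia, 0.288 to 0.464 in wrky22-ko2), so the times are not independent repeats. After the scaling by the slope, PSK1 was not called at 3 h, and 0 genes were called at 6 h. The oligopeptide transporter gene OPT1 differed by -1.50 at both times, NUDX25 by -1.38 at 3 h and -1.08 at 6 h, and the phytosulfokine precursor gene PSK1 by -0.81 and -1.02. MYB30, a transcription factor gene of defence responses, differed by -0.70 at 3 h.

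In the Columbia control channels, WRKY22 stood higher on replicate 1 than on the other replicates at each time, at 9.16, 9.19 and 9.21 at 1, 3 and 6 h. These channels of replicate 1 deviated together across the times (correlations of 0.763 to 0.807). Whether they share control RNA is not stated, so the values need not be independent.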
